A study of Mus musculus with 12 samples.

How the data were processed

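Gene expression was measured with a mouse gene array in 12 samples of sorted leukaemic cells. The samples came from 6 mouse leukaemias induced by MLL-AF9, a fusion oncogene of acute myeloid leukaemia. The labels put 3 leukaemias in a wild-type group and 3 in a Dnmt3b knock-in group, and each leukaemia gave 1 c-kit-positive and 1 c-kit-negative sample. This made 4 groups of 3 arrays. Total RNA was extracted with a column kit and labelled with an Affymetrix whole-transcript method, per the labels. Titles and descriptions name bone marrow, whereas the source field names leukaemic spleen, and the tissue is left open here.

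The deposited table held log2 RMA values for 41345 probe sets on the 12 arrays, and 0 columns of other samples. Per the submitters' processing notes, the values were made with RMA in Affymetrix Expression Console, with no versions given. The log2 scale rests on those notes and on the range of the values, since no scanner files were compared. Values were used as deposited, without a further normalization. Pearson correlation between arrays of a group was 0.933 to 0.986, the lowest between any pair of arrays was 0.928, and at most 0.0411% of values were identical between a pair of arrays.

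A probe annotation listed a gene for 25335 probe sets, of which 23521 had exactly 1 symbol and 1814 had several. Another 16010 probe sets were not listed. The Entrez identifier matched a RefSeq gene for 23328 of the probe sets with 1 symbol. For each gene the probe set with the highest mean over all arrays was kept, which gave 22180 genes, 1082 of which had more than 1 probe set. Genes were tested if their value exceeded log2 4.61, the 25th percentile of the table, on at least 3 arrays. This left 19152 genes and removed 3028.

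One limma model (version 3.58.1 in R 4.3.3, with statmod 1.5.0) was fitted to the 12 arrays with 4 group means and a shared estimate of the spread, using lmFit, contrasts.fit and eBayes with default settings. Its contrasts compared knock-in with wild type in each c-kit fraction, c-kit-positive with c-kit-negative cells in each genotype and over both, and the interaction of genotype and fraction. The genotype comparison over both fractions used the mean of both arrays of each leukaemia, 3 against 3. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05 with no minimum fold. The p-values of the genotype comparison over both fractions measure the spread between leukaemias. The 12-array model treats all arrays as independent and leaves out the pairing of both fractions of a leukaemia. Where both arrays of a leukaemia vary together, this makes its c-kit and interaction tests cautious. The labels do not state whether each leukaemia number is a separate mouse. For arrays there is no depth, so the number of arrays limits the precision.

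Both fractions of a leukaemia carry its number in the labels. After the group means were removed, the correlation between both arrays of a leukaemia was 0.279 to 0.601. Across the fractions, correlations between different leukaemias of the same genotype were negative, the highest at -0.0359. Removing the means makes the deviations within a group cancel, so a positive correlation within leukaemias pushes those between leukaemias below it. The negative sign is therefore not separate evidence of the pairing. Given the shared numbers and the positive correlation between both arrays of a leukaemia, the leukaemia number was used as a replicate block in an alternative fit. The block was fixed for the c-kit contrasts and the interaction and random for the genotype contrasts.

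The model, the filter, the threshold, the alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. The lists held 571 symbols, of which 519 were measured and 478 were tested. They covered DNA methylation and chromatin factors, genes controlled by DNA methylation, MLL-AF9 targets, stem cells, the myeloid, lymphoid, erythroid and other cell types a sort may hold, the cell cycle, metabolism, and signalling. The 28 lists with at least 5 genes were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fry test was run beside it and asks whether the genes of a list move on balance in a direction, without comparing them with other genes. Members were also tested with p-values adjusted over the list alone.

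Named genes were Dnmt3b and Kit in every comparison, plus up to 8 genes per direction with the largest difference among those past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, the 5 with the smallest p were added and are said not to pass. From each list described, up to 4 members with the smallest p were named, plus members past the threshold against the direction of the list. Predicted genes without a name and receptor or immunoglobulin segments were passed over. Dnmt3b was also compared with a two-sided exact permutation test on the means of the leukaemias. A list median has the SD of its members beside it, not an error over arrays.

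The pipeline was tested on simulated data in which 200 of 19152 genes were changed. For a change of log2 1 it recovered 93.0% in the knock-in comparison of c-kit-positive cells, 97.1% in that of c-kit-negative cells, 97.1% and 94.6% in the c-kit comparisons of wild-type and knock-in leukaemias, and 71.0% in the interaction. For a change of log2 0.5 these shares were 29.5%, 26.7%, 23.9%, 40.3% and 5.26%. Between 9 and 15 genes were called wrongly per comparison, and 0 were called with the wrong sign. The simulated arrays were drawn independently, without a correlation between both arrays of a leukaemia and without arrays that stand apart. These shares therefore describe the pipeline under that setting and may not hold for the real arrays.

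Alternatives were the replicate block, a fit to the arrays compared alone, repeated quantile normalization, centring each array on its median, no filter, a filter at log2 5.63 that kept 13416 genes, all probe sets in place of 1 per gene, a trended and robust variance, array weights, a minimum difference of 2-fold, and leaving out each leukaemia in turn. Leaving out the c-kit-negative array of knock-in leukaemia 85 was added after the data were seen, as were values without leukaemia 81 for single members of lists. Probe sets with several or no gene names were left out of the comparisons between groups because they cannot be assigned to 1 gene.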

Results

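The data were 12 arrays of sorted cells from 6 mouse leukaemias driven by the MLL-AF9 fusion. Leukaemias 73, 75 and 79 were labelled wild type and leukaemias 81, 83 and 85 were labelled Dnmt3b knock-in. Each gave a c-kit-positive and a c-kit-negative array, so that 3 arrays stood in each of 4 groups. Dnmt3b is a de novo DNA methyltransferase, and the series addresses how its overexpression bears on expression and leukaemia development. The protein c-kit is the stem cell factor receptor of immature blood cells. Median log2 values of the c-kit-positive arrays were 5.62, 5.60 and 5.56 in leukaemias 73, 75 and 79, and 5.60, 5.62 and 5.66 in leukaemias 81, 83 and 85. The c-kit-negative arrays had medians of 5.66, 5.65 and 5.63 in the wild-type leukaemias and 5.61, 5.66 and 5.71 in the knock-in leukaemias. Leukaemia 81 differed from the other arrays in Xist, the RNA of the inactive X chromosome. Its mean was 6.29, against 9.83 to 11.7 on the other arrays, with no sex given in the labels.

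Dnmt3b RNA (probe set 17377963) was not detectably higher in the leukaemias labelled knock-in. Its log2 level was 6.39 ± 0.085 (SD, n = 3 leukaemias) in these and 6.36 ± 0.12 (SD, n = 3 leukaemias) in the wild-type leukaemias. The difference of 0.03 had a 95% confidence interval of -0.19 to 0.25, or 0.878-fold to 1.19-fold, and an adjusted p of 0.964 with limma. A two-sided exact permutation test over the 6 leukaemias gave p = 0.8, where 0.1 is the smallest p that it allows. Below, the knock-in label only names the groups. The maintenance methyltransferase Dnmt1 differed by -0.13 (95% confidence interval -0.65 to 0.38) and the de novo enzyme Dnmt3a by 0.00. Kit (probe set 17438272) followed the sort. It was 2.83-fold higher in c-kit-positive cells of the wild-type leukaemias (SE 0.13 on the log2 scale, adjusted p = 0.000437) and 2.48-fold higher in those of the knock-in leukaemias (log2 1.31, SE 0.13, adjusted p = 0.000373). Between the genotypes Kit differed by -0.06 over both fractions (adjusted p = 0.900).

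**Figure D1:**
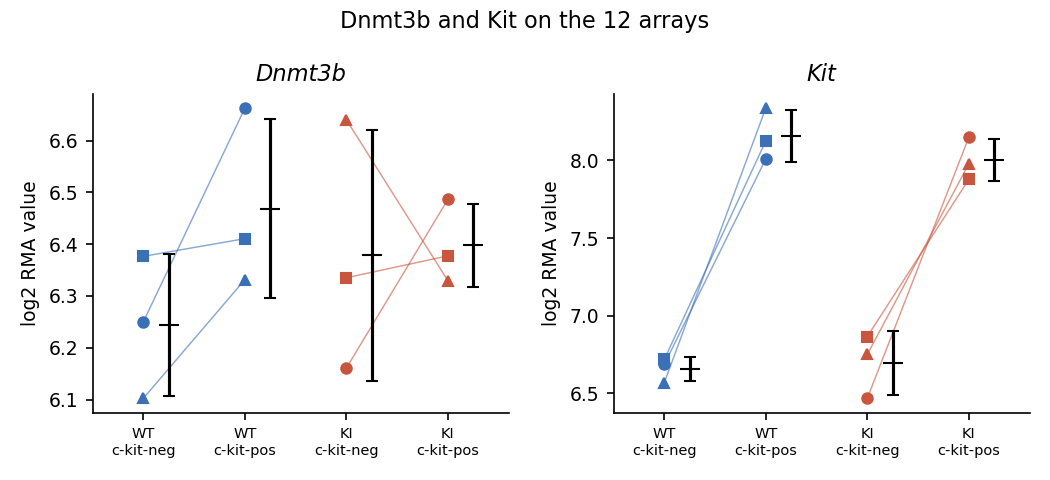
Log2 RMA values (y axis) of Dnmt3b and Kit in the 4 groups of 3 arrays (x axis; WT, wild type; KI, leukaemias labelled knock-in); points are arrays, lines join both fractions of a leukaemia, and bars show the mean ± SD. Kit was above its c-kit-negative partner in all 6 leukaemias, whereas Dnmt3b group means lay between 6.24 and 6.47 with overlapping arrays.

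In c-kit-positive cells, several genes of secondary granules and late neutrophils were higher in the leukaemias labelled knock-in. Ltf, which encodes the secondary granule protein lactoferrin, was 5.56-fold higher (log2 2.48, SE 0.30, n = 3 arrays per group, adjusted p = 0.0071 with limma). Ly6g, a surface protein of mouse neutrophils, was 4.27-fold higher, and Chil1, a chitinase-like secreted protein, was 3.68-fold higher. S100a8, a subunit of calprotectin, was 3.49-fold higher, the lysozyme gene Lyz2 2.45-fold, and the formyl peptide receptor gene Fpr2 2.22-fold. Also higher were Lipg, which encodes endothelial lipase (3.10-fold), and Mecom, which encodes the stem cell transcription factor Evi1 (2.24-fold, SE 0.19 on the log2 scale, adjusted p = 0.0304).

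Of the 16 genes with lower levels in the same comparison, 8 are named. Cst7, a cysteine protease inhibitor of granules, was 3.75-fold lower (log2 -1.91, SE 0.33, n = 3 arrays per group, adjusted p = 0.0464 with limma), and Fech, which encodes the last enzyme of haem synthesis, was 2.36-fold lower. Pgrmc1, a haem-binding membrane protein, was 2.25-fold lower. Suclg2, which encodes a subunit of mitochondrial succinyl-CoA ligase, was 1.79-fold lower, the lysine methyltransferase gene Smyd2 1.81-fold, Gsto1, a glutathione transferase gene, 1.91-fold, and Cercam 1.76-fold. One probe set of H2-Q10, a class Ib histocompatibility gene, was 3.35-fold lower, while another probe set named for this gene differed by 0.033 over both fractions.

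Of 30 tested genes of secondary granules and late neutrophils, 3 rose in c-kit-positive cells over all genes tested (Ltf, Ly6g and S100a8) and 0 fell. When adjusted over the list alone, 14 rose. The 30 genes had a median log2 difference of 0.58 (SD of members 0.714). Camera gave an adjusted p of 2.38e-14, and the adjusted p was 0.101 with an estimated correlation. Lrg1, a neutrophil granule glycoprotein, had 0.90 (adjusted p = 0.076). The 24 genes of MYC targets and ribosome biogenesis shifted down, with a median of -0.54, although 0 passed singly and 20 fell when adjusted over the list alone. Dkc1 had -0.99, Srm -0.96, Mybbp1a -0.91 and Noc4l -0.56. Camera gave an adjusted p of 4.07e-20 for this list, and the adjusted p was 0.286 with an estimated correlation. The 23 oxidative phosphorylation genes had a median of -0.29 (camera adjusted p = 4.67e-08, adjusted p = 0.577 with an estimated correlation), with 0 past the threshold singly and 3 lower when adjusted over the list alone. Atp5b had -0.57, Uqcrc1 -0.52, Atp5a1 -0.67 and Ndufb5 -0.43. Mitosis genes had a small positive median of 0.13 (camera adjusted p = 0.0276, adjusted p = 0.749 with an estimated correlation), which lost its call without leukaemia 73, 75 or 81 (adjusted p = 0.186, 0.111 and 0.328). Medians in these fits were 0.075, 0.14 and 0.045. Among MLL-AF9 target genes, Mecom rose and 18 of 19 did not pass, with Hoxa9 at -0.65 and Hoxa7 at -0.48. The fry test passed 1 of 28 lists.

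In all, 27 of 19152 genes passed the threshold in c-kit-positive cells, 11 higher and 16 lower in the leukaemias labelled knock-in, and 12 of them differed at least 2-fold. Groups did not overlap for 17.4% of genes, where chance gives 10%. The count was 3 without leukaemia 75, 1 without leukaemia 79, 123 (14 higher and 109 lower) without leukaemia 81 and 0 without leukaemia 83, and it turned to 13 higher and 9 lower without 73 and to 12 and 10 without 85. Each of the 16 named genes past the threshold lost its call without at least 1 of the leukaemias, 5 of them (S100a8, Lyz2, Fpr2, Cst7 and Gsto1) lost it under another scaling of the arrays, and the replicate block gave 23 genes.

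In c-kit-negative cells, Ltf was 7.04-fold higher in the leukaemias labelled knock-in (log2 2.82, SE 0.30, n = 3 arrays per group, adjusted p = 0.00356 with limma), Ly6g was 6.07-fold higher (adjusted p = 0.000772) and Chil1 3.86-fold higher (adjusted p = 0.00862). The antiviral membrane protein gene Ifitm3 was 2.99-fold higher, and Cxcr2, the receptor through which neutrophils follow chemokines, was 2.48-fold higher. Fpr2 rose 2.43-fold, Mecom 2.22-fold and Wfdc21 2.13-fold. H2-Q10, read by the same probe set as in c-kit-positive cells, was the 1 gene past the threshold in the other direction, at 3.35-fold lower. The next genes by p were Fundc2 at -0.84 (adjusted p = 0.109), Blm, a DNA helicase, at -0.52 (adjusted p = 0.165), P2rx1 at -0.62 (adjusted p = 0.222) and Cercam at -0.61 (adjusted p = 0.233), which did not pass.

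Late neutrophil genes had a median of 0.53 in c-kit-negative cells (SD of members 0.869), with 4 of 30 higher (Ltf, Ly6g, Cxcr2 and Wfdc21), or 10 higher and 1 lower when adjusted over the list alone. Camera gave an adjusted p of 9.73e-16, and the adjusted p was 0.073 with an estimated correlation. The 18 type I interferon response genes had a median of 0.34 (camera adjusted p = 3.24e-10, adjusted p = 0.235 with an estimated correlation). None of them passed singly with limma and 5 rose when adjusted over the list alone. The nucleic acid sensor gene Zbp1 had 0.76, Oasl2 0.72, Oas3 0.60 and Parp14 0.51, or 0.64, 0.45, 0.42 and 0.33 without leukaemia 81. Mitosis genes were lower by a median of -0.36 (camera adjusted p = 9.75e-11, adjusted p = 0.447 with an estimated correlation). Aurkb, the kinase of the chromosomal passenger complex, had -0.68, Ccnb2 -0.62, Tpx2 -0.53 and Cenpa -0.46. Leukaemia 81 was not lower in every member. Its Kif11 (7.72), Mki67 (9.17) and Cdk1 (8.09) lay within the wild-type values (7.04 to 8.01, 8.86 to 9.64 and 7.61 to 8.45). For these genes leukaemias 83 (6.85, 8.80 and 7.20) and 85 (6.44, 8.23 and 6.94) lay below them. Oxidative phosphorylation and MYC target genes both had a median of -0.23 (camera adjusted p = 9.83e-09 and 1.47e-05, with adjusted p = 0.425 and 0.602 with an estimated correlation), and S phase genes had -0.19 (0.00156 and 0.674). Markers of B cells, at a median of 0.11, and of T and NK cells, at 0.10, moved with the genotype (camera adjusted p = 0.000776 and 0.00138, and adjusted p = 0.235 for each with an estimated correlation). Ighm, an immunoglobulin heavy chain gene, had 1.09, and Cd79a, Cd3e and Thy1 had 0.37, 0.46 and 0.34, or 0.65, 0.19, 0.28 and 0.29 in this order without leukaemia 81. Inflammatory cytokine genes had a median of 0.19 (camera adjusted p = 0.00741, adjusted p = 0.602 with an estimated correlation), with the chemokine gene Ccl5 at 1.02 (adjusted p = 0.788), or 0.30 without leukaemia 81. The fry test passed 0 of 28 lists. The camera call of the B cell list was lost without leukaemia 81 (adjusted p = 0.115), that of the S phase list without 79 or 85 (0.417 and 0.793) and that of the inflammatory list without 79 or 83 (0.0883 and 0.904). Medians in these fits were 0.11 for the B cell list, -0.084 and -0.033 for the S phase list, and 0.20 and 0.033 for the inflammatory list. Without the c-kit-negative array of leukaemia 85, MYC target genes (median -0.16, adjusted p = 0.0773) and S phase genes (-0.03, 0.891) did not pass.

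In c-kit-negative cells 12 genes passed the threshold, 11 higher and 1 lower, and 11 of them differed at least 2-fold. An unadjusted p under 0.05 was reached by 1168 genes, where chance gives 958, with 447 of them higher and 721 lower. Groups did not overlap for 8.88% of genes, where chance gives 10%. Of the 11 genes higher in each fraction, 6 were shared, where chance gives 0.00632, but both fractions come from the same leukaemias. The count was 3 without leukaemia 73, 3 without 75, 5 without 79, 4 without 83 and 29 without 85, and without 81 it was 83, with the balance turned to 16 higher and 67 lower. Without the c-kit-negative array of leukaemia 85 it was 23, in a fit to these 6 arrays alone it was 1, and only Ltf and Ly6g of the 9 named genes past the threshold kept their calls without each leukaemia in turn, while Ifitm3, Mecom and H2-Q10 lost theirs under another scaling of the arrays.

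**Figure D2:**
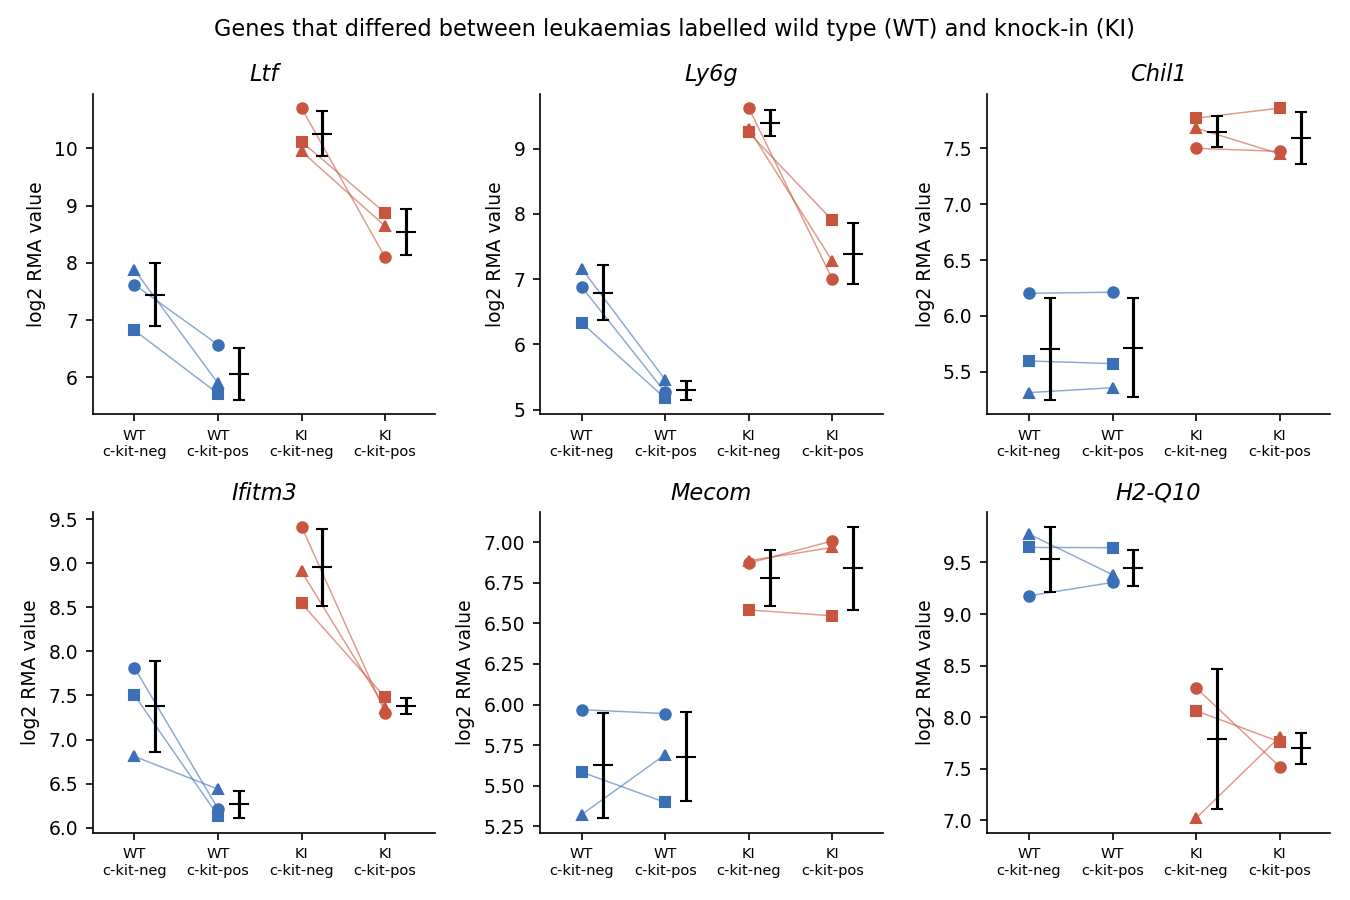
Log2 RMA values (y axis) of 6 genes past the threshold between genotypes, in the 4 groups of 3 arrays (x axis; WT, wild type; KI, labelled knock-in); points are arrays, lines join both fractions of a leukaemia, and bars show the mean ± SD. For Ltf, Ly6g, Chil1, Ifitm3 and Mecom every KI array lay above every WT array of the same fraction, and the H2-Q10 probe set was lower, with its lowest WT array at 9.18 and its highest KI array at 8.29.

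Over both fractions, Ltf was 6.26-fold higher in the leukaemias labelled knock-in (log2 2.65, SE 0.19, n = 3 leukaemias per group, adjusted p = 0.00398 with limma) and Ly6g 5.09-fold higher (adjusted p = 0.00272). Chil1 was 3.77-fold higher and Ifitm3 2.55-fold higher. The H2-Q10 probe set kept for that gene was 3.35-fold lower, while the other probe set named for it differed by 0.033. Flt3, a cytokine receptor of progenitors, was 2.90-fold lower without passing (adjusted p = 0.111). Slfn2 at 0.85 (0.0788), Pgrmc1 at -0.81 (0.0761), and Got2 at -0.70 and Cercam at -0.71 (adjusted p = 0.111 for both) did not pass either.

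Late neutrophil genes had a median of 0.67 over both fractions (SD of members 0.715), and 2 of 30 rose (Ltf and Ly6g), or 17 when adjusted over the list alone. The camera adjusted p was 2.06e-17, and the adjusted p was 0.201 with an estimated correlation. MYC target and ribosome biogenesis genes had a median of -0.39, with 0 past the threshold singly and 14 lower when adjusted over the list alone. Mybbp1a had -0.80, Dkc1 -0.69 and Pes1 -0.43 (camera adjusted p = 2.2e-15, adjusted p = 0.429 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.27 and interferon genes 0.21 (camera adjusted p = 1.34e-10 and 7.53e-07, and adjusted p = 0.429 for each with an estimated correlation). B cell genes at 0.12, T and NK cell genes at 0.08 and S phase genes at -0.10 were also past the camera threshold, but not with an estimated correlation (adjusted p = 0.429, 0.536 and 0.898). Primary granule genes, the earlier granule set, had a median of 0.20 and monocyte genes -0.03, and neither passed camera. The B cell call was lost without leukaemia 81 (adjusted p = 0.150), the S phase call without 79 or 85 (0.522 and 0.486) and the T and NK cell call without 79, 81 or 85 (0.172, 0.0507 and 0.169), and repeated quantile normalization ended all 3. Medians in these leave-outs, in that order, were 0.083 for B cell, -0.062 and -0.008 for S phase, and 0.063, 0.097 and 0.044 for T and NK cell genes. With the normalization, B cell, S phase, and T and NK cell genes had 0.11, -0.11 and 0.06. Without leukaemia 75, 12 lists passed in place of 7.

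Over both fractions 5 genes passed the threshold, 4 higher and 1 lower, and 1603 had an unadjusted p under 0.05, where chance gives 958, with 453 of them higher and 1150 lower. Groups did not overlap for 2485 of the 19152 genes, where chance gives 10%. The count was 2 without leukaemia 75, 79 or 83, 17 without 85 and 115 without 81, of which 14 were higher and the rest lower, and it was 34 with the leukaemia as a random block. Centring each array on its median left 2 genes, Chil1, Ifitm3 and H2-Q10 lost their calls under another scaling, and only Ltf and Ly6g kept theirs without each leukaemia in turn.

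The question of how c-kit-positive cells differ from c-kit-negative cells was first asked in the wild-type leukaemias. Mpo, which encodes the primary granule enzyme myeloperoxidase, was 8.87-fold higher in c-kit-positive cells (log2 3.15, SE 0.65, n = 3 arrays per group, adjusted p = 0.0465 with limma). Nkg7, a granule membrane protein gene, was 4.68-fold higher, the fatty acyl-CoA reductase gene Far2 4.50-fold, and the ubiquitin ligase gene Nedd4 3.25-fold. The histone gene H2bc9 rose as well, from c-kit-negative values close to the filter value (4.58 to 4.77). Mgam, which encodes maltase-glucoamylase, was 3.07-fold higher and Retsat, which encodes retinol saturase, 2.79-fold. Fn1, the fibronectin gene, was 12.8-fold lower (log2 -3.68, SE 0.34, adjusted p = 0.000598), and the calcium-binding protein gene S100a6 was 8.34-fold lower. The neutrophil proteases Mmp9 and Mmp8 were 6.44-fold and 5.94-fold lower. The inhibitory receptor gene Lilrb4a was 4.30-fold lower, Wfdc17 4.28-fold and Ifitm6 4.05-fold. Stfa2 fell as well, to c-kit-positive values of 4.20 to 5.83, of which 1 lay below the filter value.

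Of 14 primary granule genes, 3 rose in c-kit-positive wild-type cells (Nkg7, Clec12a and Mpo), or 11 when adjusted over the list alone, with a median of 0.93 (camera adjusted p = 2.23e-11, adjusted p = 0.172 with an estimated correlation). Ctsg, which encodes cathepsin G, had 1.76 (adjusted p = 0.086). Of 30 late neutrophil genes, 6 fell, among them Ly6g (-1.49) and Lcn2 (-0.91), or 18 when adjusted over the list alone. Their median was -0.89 (camera adjusted p = 2.24e-12, adjusted p = 0.127 with an estimated correlation). Of 25 monocyte and macrophage genes, 2 fell, Fn1 and Lgals3 (-1.34), and Ctss had -1.73 and Cd14 -0.79 without passing. The list had a median of -0.26 (camera adjusted p = 4.11e-06, adjusted p = 0.127 with an estimated correlation), and 6 fell when adjusted over the list alone. Mitosis genes had a median of 0.59, with 0 past the threshold singly and 24 of 25 higher when adjusted over the list alone. Aurkb had 0.94, Cdk1 0.99 and Birc5 0.77 (camera adjusted p = 9.05e-16, adjusted p = 0.249 with an estimated correlation). MYC target genes had 0.53 and S phase genes 0.48 (camera adjusted p = 3.58e-14 and 6.15e-09, and adjusted p = 0.246 and 0.294 with an estimated correlation). Noc4l was the 1 MYC target past the threshold, and 19 MYC target and 6 S phase genes rose when adjusted over the list alone. In all, 13 lists passed camera, 0 with an estimated correlation and 5 with fry.

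In wild-type leukaemias 147 genes passed, 76 higher and 71 lower, and 52 of them differed at least 2-fold. Groups did not overlap for 27.7% of genes, where chance gives 10%. With the leukaemia number as a replicate block, 2109 genes passed, 1525 higher and 584 lower, and a fit to these 6 arrays alone gave 898. The count was 1 without leukaemia 73, 662 without 81 and 569 without 85, and more genes were lower than higher without 75 (4 higher and 11 lower), 79 (36 and 42) or 83 (20 and 35). Leukaemias 81, 83 and 85 are not in this contrast and act on it only through the shared estimate of the spread. Mpo, Stfa2, Wfdc17 and Ifitm6 lost their calls under another scaling of the arrays, and Kit was the 1 of 16 named genes that kept its call without each leukaemia in turn.

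In the leukaemias labelled knock-in, Far2 had the largest difference among the named genes higher in c-kit-positive cells, at 3.55-fold (log2 1.83, SE 0.33, n = 3 arrays per group, adjusted p = 0.0117 with limma). Cdk1, the kinase that drives entry into mitosis, was 3.21-fold higher (adjusted p = 0.00453). Top2a, a DNA topoisomerase, was 3.16-fold higher, the cytokinesis gene Ect2 3.06-fold, the spindle motor gene Kif11 2.90-fold and the proliferation marker Mki67 2.84-fold. Nkg7 was 2.93-fold higher and the histone gene H2bc12 2.84-fold. Mmp8 was 11.7-fold lower (log2 -3.55, SE 0.28, adjusted p = 0.000105), Fn1 11.4-fold, S100a6 8.88-fold, the resistin-like gene Retnlg 8.10-fold and Mmp9 6.75-fold. Pld4 was 7.50-fold lower, Wfdc17 5.94-fold, and Ifi30, a lysosomal thiol reductase gene, 5.64-fold.

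Of 25 mitosis genes, 24 rose in c-kit-positive cells of these leukaemias, with a median of 1.18 (SD of members 0.286). Cenpf had 0.88 and Aurkb 1.34. Camera gave an adjusted p of 2.35e-40, and the adjusted p was 0.0801 with an estimated correlation. Of 25 monocyte genes, 6 fell, among them Lgals3 (-1.27), the macrophage growth factor receptor gene Csf1r (-1.78) and the chemokine receptor gene Ccr2 (-0.71), or 13 when adjusted over the list alone. This list had a median of -0.59 and was the 1 list past the threshold with an estimated correlation (camera adjusted p = 2.26e-10, adjusted p = 0.0478 with an estimated correlation). Late neutrophil genes had a median of -0.47 and 8 of 30 fell, among them Cxcr2 (-1.66) and Ly6g (-2.00), or 13 when adjusted over the list alone (camera adjusted p = 1.14e-10, adjusted p = 0.0801 with an estimated correlation). Primary granule genes had a median of 1.13, and 3 of 14 rose, Prss57 (1.03), Nkg7 and Clec12a (0.65), or 9 when adjusted over the list alone (camera adjusted p = 5.33e-09, adjusted p = 0.133 with an estimated correlation). S phase genes had a median of 0.57 and 3 rose, the ribonucleotide reductase genes Rrm2 (0.90) and Rrm1 (1.28) and the helicase gene Mcm7 (0.87), or 15 when adjusted over the list alone (camera adjusted p = 1.53e-13, adjusted p = 0.133 with an estimated correlation). Immediate early genes had -0.77 and inflammatory cytokine genes -0.50, with Nr4a1 (-1.35), Btg2 (-1.01) and Il1b (-1.53) lower. Camera gave 7.43e-07 and 1.53e-07 for these lists, with an adjusted p of 0.205 and 0.133 with an estimated correlation. Interferon genes had -0.24, with Zbp1 (-0.72) and Irf7 (-0.69) lower (camera adjusted p = 2.04e-05, adjusted p = 0.21 with an estimated correlation). In all, 15 lists passed camera and 9 passed fry.

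In the leukaemias labelled knock-in 360 genes passed, 216 higher and 144 lower, and 144 differed at least 2-fold. Groups did not overlap for 13.6% of genes, where chance gives 10%. With the leukaemia number as a replicate block 1666 genes passed, 1139 higher and 527 lower, and a fit to these 6 arrays alone gave 145. The count was 227 without leukaemia 73 and 228 without 75, which are not in this contrast and act on it only through the shared estimate of the spread. The balance turned to more lower genes without leukaemia 83 (58, 19 higher and 39 lower), without leukaemia 85 (120 and 155) and without its c-kit-negative array (141 and 249). H2bc12 lost its call under another scaling of the arrays, and 6 of 17 named genes (Ect2, Mmp8, Fn1, S100a6, Mmp9 and Kit) kept their calls without each leukaemia in turn.

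Averaged over both genotypes, Kit was 2.65-fold higher in c-kit-positive cells (log2 1.40, SE 0.089, n = 6 arrays per fraction, adjusted p = 7.78e-06 with limma), Mpo 7.23-fold, Far2 3.99-fold, Nkg7 3.71-fold and Cdk1 2.53-fold. The histone genes H4c17 and H1f5 were 2.56-fold and 2.45-fold higher, and H2bc9 rose without a fold given, because its c-kit-negative arrays (4.31 to 4.77) lay close to the filter value of log2 4.61. Fn1 was 12.1-fold lower, S100a6 8.60-fold, Mmp8 8.33-fold, Retnlg 6.65-fold, Mmp9 6.59-fold, Pld4 5.77-fold, Wfdc17 5.04-fold and Lilrb4a 4.89-fold. All 25 mitosis genes rose, with a median of 0.92 (camera adjusted p = 1.1e-28, adjusted p = 0.124 with an estimated correlation). Of 22 S phase genes 11 rose, including Uhrf1 (0.81), which guides maintenance DNA methylation, and 20 rose when adjusted over the list alone (median 0.55, camera adjusted p = 2.08e-12, adjusted p = 0.181 with an estimated correlation).

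Of 14 primary granule genes 9 rose over both genotypes, with a median of 0.89, or 12 when adjusted over the list alone. Of 30 late neutrophil genes 15 fell, including Ly6g (-1.75) and Cxcr2 (-1.04), with a median of -0.59, or 17 when adjusted over the list alone. Of 25 monocyte genes 12 fell, including Csf1r (-1.46), the cathepsin gene Ctss (-1.84) and Lgals3 (-1.30), with a median of -0.39, or 14 lower and 1 higher when adjusted over the list alone. Camera gave adjusted p-values of 7.31e-11, 2.08e-12 and 1.51e-08 for these lists in that order, and the adjusted p was 0.142, 0.0796 and 0.0796 with an estimated correlation. Of 24 MYC target genes 8 rose, including the nucleolin gene Ncl (0.85), Mybbp1a (0.70) and Nop58 (0.62), or 20 when adjusted over the list alone (median 0.36, camera adjusted p = 4.19e-10, adjusted p = 0.216 with an estimated correlation). Il1b (-1.32), Ccl3 (-1.50) and Nfkbiz (-1.04) fell among inflammatory genes, and Nr4a1 (-1.34), Junb (-0.74) and Atf3 (-0.80) among immediate early genes. These lists had medians of -0.35 and -0.60 (camera adjusted p = 2.5e-06 and 0.000125, adjusted p = 0.181 and 0.305 with an estimated correlation). In all, 17 lists passed camera, 0 with an estimated correlation and 12 with fry.

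Over both genotypes 1580 genes passed, 1118 higher and 462 lower, and 134 differed at least 2-fold. The replicate block gave 3758 genes, 2492 higher and 1266 lower. The count was 543 without leukaemia 73, 503 without 75, 1026 without 79 and 568 without 83, and 15 of 16 named genes kept their calls without each leukaemia in turn.

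Of the genes past the threshold in each genotype, 42 higher genes were shared (76 and 216 called, 0.857 shared by chance) and 48 lower genes (71 and 144 called, 0.534 by chance). Both contrasts share the estimate of each gene's spread, so the calls are not independent as the chance values assume. Across 19152 genes, which are not independent replicates, the c-kit differences of both genotypes had a Pearson r of 0.753 and a Spearman rho of 0.608, with 72.5% of signs shared. The genotype differences in both fractions, which come from the same leukaemias, had an r of 0.562 and a rho of 0.429.

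**Figure D3:**
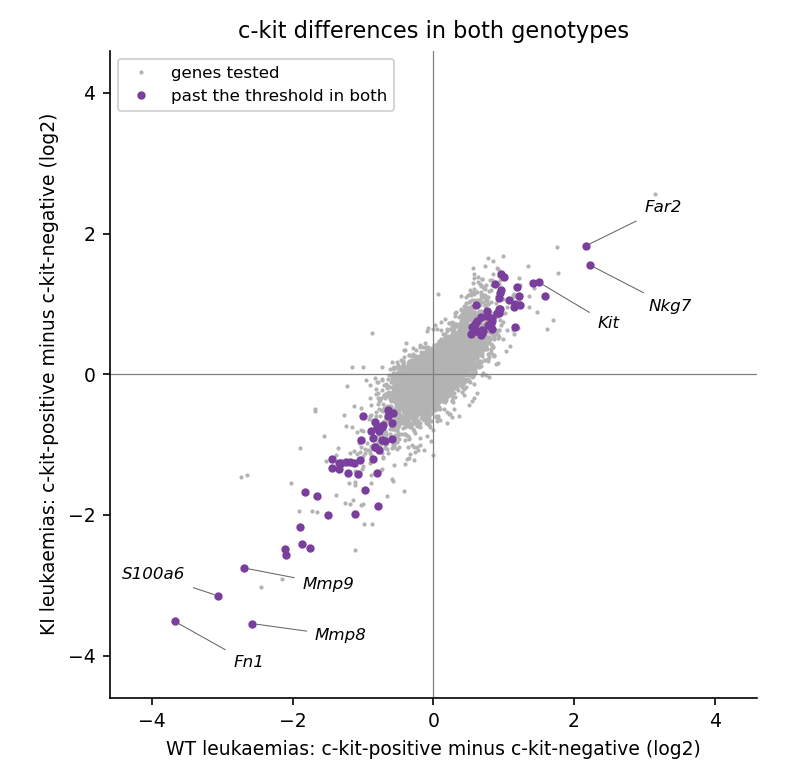
Log2 difference between c-kit-positive and c-kit-negative cells in wild-type leukaemias (x axis) and in leukaemias labelled knock-in (y axis), where grey points are the 19152 genes tested and purple points the genes past the threshold in both. Fn1 (-3.68 and -3.51) lies near the diagonal, and Mmp8 (-2.57 and -3.55) and Nkg7 (2.23 and 1.55) lie further from it with the same sign in both genotypes, with r = 0.753 across genes.

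Whether the c-kit difference depends on the genotype was tested as an interaction. Mitosis genes had a larger c-kit difference in the leukaemias labelled knock-in, with a median interaction of 0.53 on the log2 scale (SD of members 0.207, camera adjusted p = 2.28e-17, adjusted p = 0.747 with an estimated correlation). Mki67 had 0.94 and Cenpf 0.57, and 0 of 25 passed singly with limma or when adjusted over the list alone. MYC target genes had a smaller c-kit difference, at -0.32, with Ppan at -0.44 and Noc4l at -0.41 (camera adjusted p = 1.46e-09, adjusted p = 0.747 with an estimated correlation). Interferon genes had -0.20 (0.000891, and 0.747 with an estimated correlation), and late neutrophil genes had 0.11, which did not pass camera (adjusted p = 0.764). The smallest p-values belonged to Clec4a3 (-1.08) and the methyltransferase gene Smyd2 (-0.83), both at an adjusted p of 0.735, and Cxcr2 had -1.25 (SE 0.25, adjusted p = 1.0).

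For the interaction 0 genes passed with limma, while 427 had an unadjusted p under 0.05 where chance gives 958, and the replicate block also gave 0. Leaving out leukaemia 85 gave 1 gene. In all, 5 lists passed camera, 0 with an estimated correlation and 0 with fry, and the block gave 8 lists. Leaving out the c-kit-negative array of leukaemia 85 gave 9 lists, leaving out leukaemia 75 gave 8, and leaving out leukaemia 81 gave 3, without the interferon list (adjusted p = 0.161).

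**Figure D4:**
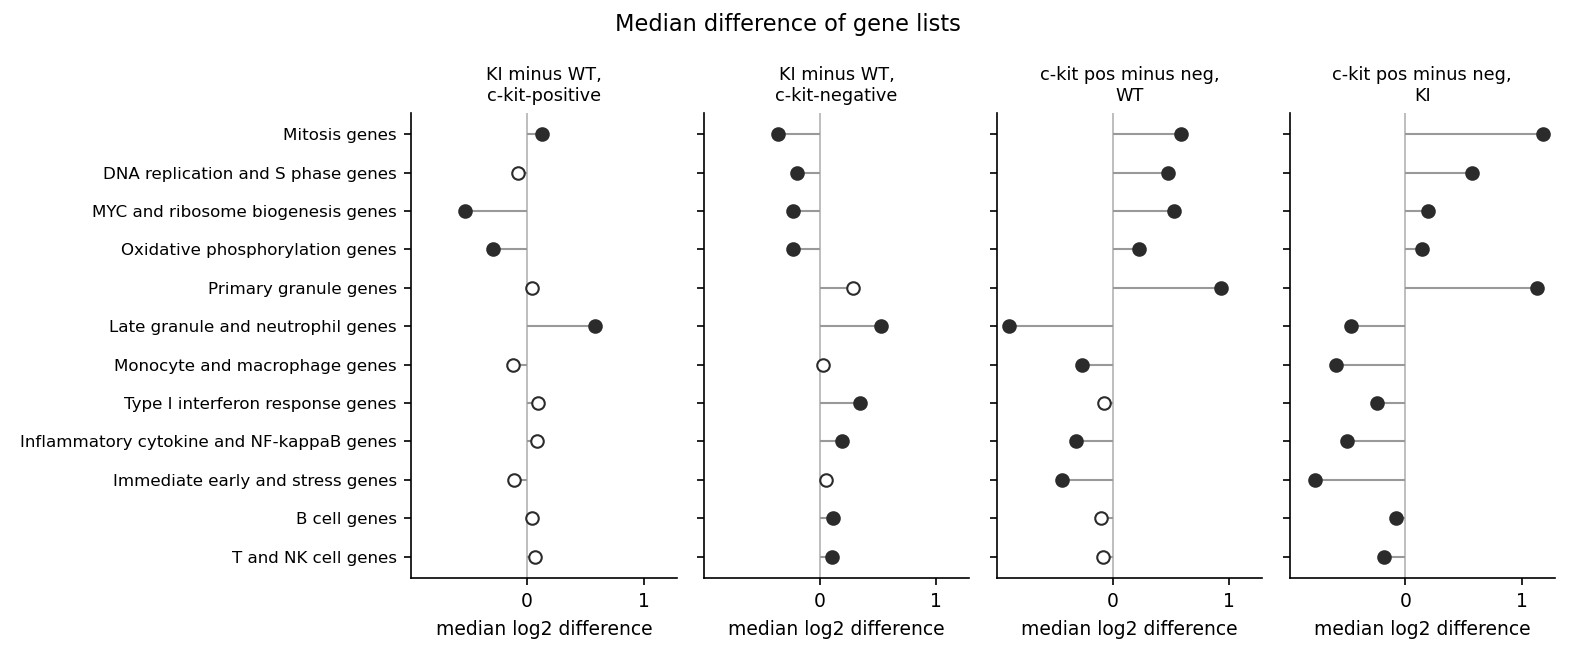
Median log2 difference (x axis) of the members of 12 gene lists (y axis), in panels for knock-in against wild type in each c-kit fraction and for c-kit-positive against c-kit-negative cells in each genotype; filled points passed camera at a preset correlation and open points did not. Late neutrophil genes had medians of 0.58 and 0.53 between genotypes and -0.89 and -0.47 between fractions, and mitosis genes 0.59 and 1.18 between fractions, and with an estimated correlation none of these 6 passed (adjusted p = 0.101, 0.073, 0.127, 0.0801, 0.249 and 0.0801).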

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

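Leaving out the c-kit-negative array of leukaemia 85 was chosen after the data were seen. In the interaction test of c-kit difference and genotype, 5 gene lists passed camera at a preset correlation, while 0 passed with an estimated correlation and 0 with fry. Mitosis genes had a median interaction of 0.53 on the log2 scale (camera adjusted p = 2.28e-17), and MYC target and ribosome biogenesis genes had -0.32 (1.46e-09). Immediate early and stress genes had -0.31 (0.00604), class II antigen presentation genes -0.22 (0.0218) and type I interferon response genes -0.20 (0.000891). With an estimated correlation the adjusted p was 0.797 for immediate early genes and 0.747 for each of the others, and fry gave an adjusted p of 0.920 for each. With that array left out, 9 lists passed in place of 5. Calls were lost without leukaemia 81 for the interferon (adjusted p = 0.161), class II (0.594) and immediate early (0.0642) lists, without 79 for class II (0.70) and without 73 for immediate early genes (0.0617).

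In Mdm1 and Psg21, all 3 wild-type leukaemias moved one way between the c-kit fractions and all 3 leukaemias labelled knock-in the other way. The c-kit difference was 0.58 larger in the knock-in group for Mdm1 and 0.64 larger for Psg21 on the log2 scale. The pattern was looked for among named genes only, and both were named for a small interaction p from these same values. The opposite directions as such were not tested, and the interaction test gave an adjusted p of 1.0 for both genes with limma.

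Genes of the Y chromosome, which were used in no comparison, had signal in leukaemia 81 above the level of the other arrays. Its mean log2 value was 6.07 for Eif2s3y, where the other arrays had 3.37 to 3.54. The histone demethylase gene Kdm5d had 5.37 (others 3.24 to 3.63) and Uty had 6.18 (others 3.19 to 3.45). The same leukaemia had the low Xist value given with the data.

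Probe sets without a single gene name, which were also left out of the comparisons, held differences between the c-kit fractions. Of 12086 such probe sets tested with limma, 42 passed the threshold over both genotypes, 32 higher and 10 lower in c-kit-positive cells, 2 passed in the wild-type leukaemias and 1 in those labelled knock-in. In the genotype comparisons and the interaction 0 passed, with 779, 602, 686 and 357 at an unadjusted p under 0.05 in c-kit-positive cells, in c-kit-negative cells, over both fractions and in the interaction. Chance gives a share of 0.05 of the 12086 probe sets. The count in c-kit-negative cells lay close to that share, the interaction count lay below it, and the other counts lay above it.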

How the results depend on the processing

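Fits without the c-kit-negative array of leukaemia 85, and the fit of the stem and progenitor list members without leukaemia 79, were chosen after the data were seen. Counts are of genes past the threshold, with the main value first, and where a count moved the cause was not tested unless stated. Named genes were followed under the block, both scalings, the trended robust variance and the fits without a leukaemia or the array of 85, and 0 of their calls reversed in these. A comparison with another Dnmt3b probe set was not run, because the table holds 1.

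With the leukaemia number as a replicate block, genes went from 5 to 34 for the genotype over both fractions, from 147 to 2109 for c-kit in wild-type leukaemias, from 360 to 1666 in the leukaemias labelled knock-in and from 1580 to 3758 over both. The block gave 8 interaction lists in place of 5 and moved no other count by over 1.5 times. In the genotype comparisons, the random block ended 1 call of a named gene and brought 3 that had not passed past the threshold. Averaging all 12 arrays without a block gave 162 (53 higher and 109 lower) for the genotype over both fractions, which treats both arrays of a leukaemia as independent. A fit to the arrays compared alone gave 64 (main 27) for the genotype in c-kit-positive cells, 1 (main 12) in c-kit-negative cells, 898 for c-kit in wild-type leukaemias and 145 in those labelled knock-in.

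Median centring gave 2 for the genotype over both fractions and 69 for c-kit in wild-type leukaemias, repeated quantile normalization gave 543 for c-kit in leukaemias labelled knock-in and 4 lists (main 7) for the genotype over both fractions, and a trended robust variance gave 9 genes there. By construction, a minimum of 2-fold left 12 for the genotype in c-kit-positive cells and 52, 144 and 134 for c-kit in wild-type leukaemias, in those labelled knock-in and over both. Without the c-kit-negative array of leukaemia 85 there were 23 genes for the genotype in c-kit-negative cells, and 1 gene and 9 lists for the interaction.

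Array weights gave 735, 3158 and 4535 genes for the genotype in c-kit-positive cells, in c-kit-negative cells and over both, 1337, 6095 and 5790 for c-kit in wild-type leukaemias, in those labelled knock-in and over both, and 5 for the interaction. They turned the genotype balance to 1351 higher and 1807 lower in c-kit-negative cells (main 11 and 1) and to 1870 and 2665 over both (main 4 and 1). In the 12-array fit the c-kit-negative array of leukaemia 83 had a weight of 21.5, where the other arrays had 0.27 to 2.40. With weights, the mean of the c-kit-negative knock-in group therefore rests largely on that 1 array. For the genotype over both fractions, leukaemia 83 had a weight of 54.3 where the others had 0.21 to 1.03, so the knock-in mean rests largely on that leukaemia. With weights, the highest other split gave 12 genes in c-kit-positive cells, 41 in c-kit-negative cells and 3032 over both fractions.

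Leaving out each leukaemia in turn gave 0 to 123 genes for the genotype in c-kit-positive cells, 3 to 83 in c-kit-negative cells and 2 to 115 over both. It gave 1 to 662 for c-kit in wild-type leukaemias, 58 to 367 in those labelled knock-in, 503 to 2087 over both, and 0 to 1 for the interaction. In the c-kit comparison of a single genotype, a leukaemia of the other genotype acts only through the shared estimate of the spread. Lists numbered 6 to 12 for the genotype over both fractions and 3 to 8 for the interaction, and the correlation of the c-kit differences was 0.678 to 0.752. The Dnmt3b difference stayed between -0.04 and 0.08. Of 79 calls of named genes 53 were lost without some leukaemia, and 26 held in all the fits in which named genes were followed.

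With an estimated correlation the lists past the threshold went from 4, 9 and 7 for the genotype in c-kit-positive cells, in c-kit-negative cells and over both to 0 in each, from 13 to 0, 15 to 1 and 17 to 0 for c-kit in wild-type leukaemias, in those labelled knock-in and over both, and from 5 to 0 for the interaction. Genes above log2 4.61 on fewer than 3 arrays were not tested. A gene passed with 1 group of arrays near or below that value, as H2bc9 did, and no test of the size of such differences was run.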

Other observations

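Tests chosen after the result was seen were the range of Dnmt3b over the leukaemias, the Dnmt3b difference between fractions, the late neutrophil genes without leukaemia 81, their medians per leukaemia and the other H2-Q10 probe set. In c-kit-positive cells over both genotypes, the maintenance methyltransferase gene Dnmt1 rose by 0.80 on the log2 scale (adjusted p = 0.024 with limma) and Uhrf1, which recruits it to replicated DNA, by 0.81 (adjusted p = 0.0072), and the methyl-binding protein gene Mbd1 rose by 0.48, while the cytidine deaminase gene Apobec1 fell by 0.45. Dnmt3b had 0.12 (adjusted p = 0.466). In all, 3 of 17 genes on that list rose and 1 fell, or 7 and 1 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00686, adjusted p = 0.305 with an estimated correlation). Of 19 polycomb genes, which encode chromatin repressors, 8 rose, including Suz12 (0.85), Rbbp7 (0.80), the methyltransferase gene Ezh2 (0.71) and Mtf2 (0.39). Their median was 0.07 and their mean 0.23 (camera adjusted p = 0.000658, adjusted p = 0.142 with an estimated correlation). Of 20 glycolysis and hypoxia genes, Vegfa (0.84), Tpi1 (0.62) and Pgam1 (0.39) were among 4 that rose and Ddit4 (-0.73) among 2 that fell, and the list did not pass camera. In the stem and progenitor list, Kit, Myb (1.01) and Nucb2 (0.60) rose, 3 of 23.

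Of the genes known to be controlled by DNA methylation, those tested had small differences between the genotypes over both fractions. The 13 tested germline genes had a median of 0.06 (camera adjusted p = 0.285), with Dazl at 0.16. The 22 tested imprinted genes had 0.07 (0.163), and 0 passed the threshold in either list with limma. Genes removed by the filter were not tested, so these medians do not cover genes below the filter value on most arrays. When adjusted over the list alone, 2 imprinted genes were higher, Igf2r (0.43) and Cdkn1c (0.48), and Impact was lower (-0.46). MLL-AF9 target genes had a median of -0.04 (0.571), and polycomb genes had -0.10 (0.113). The stem and progenitor list had a median of -0.01 (camera adjusted p = 0.0898), with 0 past the threshold over all genes tested and 4 lower when adjusted over the list alone, Flt3 (-1.54), Cd34 (-1.44), Cd93 (-0.81) and Npm1 (-0.52), while Kit had -0.06. Wild-type leukaemia 79 stood apart in Cd34 and in some mast cell and eosinophil markers. On its c-kit-positive array Cd34 was 9.54, where the other wild-type leukaemias had 7.46 and 7.28, Cpa3 was 8.58 (6.34 and 5.81), Prg2 8.39 (6.40 and 6.30) and Gata2 7.19 (5.52 and 5.09), but Ms4a2 (4.76) and Epx (5.47) were not raised. Without leukaemia 79, in a fit chosen after the data were seen, Flt3 (-1.69), Cd34 (-0.997) and Cd93 (-0.73) were still lower when adjusted over the list alone with limma (adjusted p = 0.00213, 0.00746 and 0.0148), and Npm1 (-0.42) was not (adjusted p = 0.184). None of the 4 passed over all genes tested, and the cause of the high markers was not tested.

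The first pattern weighed is that Dnmt3b was not higher in the leukaemias labelled knock-in. Labels swapped between the groups would need leukaemias of high and of low Dnmt3b, but the range over the 6 leukaemias was 0.27 on the log2 scale. This argues against a swap between leukaemias that do and do not overexpress the probed transcript, but only if the probe set follows Dnmt3b RNA. A probe set that does not follow Dnmt3b RNA stays open, since the c-kit fractions had no detectable difference to show that it responds (0.12, adjusted p = 0.466). A knock-in transcript that the probes may not cover was not tested.

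The next pattern is the higher level of late neutrophil genes in the leukaemias labelled knock-in, with a median of 0.67 over both fractions (adjusted p = 0.201 with limma camera and an estimated correlation). If it only followed a general shift along the wild-type c-kit axis, removing the position of each leukaemia on that axis would end it, but a median of 0.54 was left (SD of members 0.727, adjusted p = 2.43e-15 with limma camera, and 0.0652 with an estimated correlation), and the medians of the single leukaemias were 0.51 to 0.60 in those labelled knock-in and -0.21 to 0.05 in the wild type, which argues against that shift as the whole cause. The male-type leukaemia 81 as the cause is argued against by a median of 0.70 without it (adjusted p = 5.94e-12 with limma camera, and 0.575 with an estimated correlation), where the other leukaemias labelled knock-in had medians of 0.68 and 0.73 against -0.31 to 0.07 in the wild type. A larger share of more mature cells within the sorted fractions and an effect of the genotype remain open as hypotheses and were not tested.

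The last pattern is that 1 H2-Q10 probe set was lower in the leukaemias labelled knock-in, at 7.74 ± 0.28 against 9.49 ± 0.22 (SD, n = 3 leukaemias). Less H2-Q10 RNA would be expected to lower the other probe set too, which had 6.26 ± 0.084 and 6.23 ± 0.095 and differed by 0.033 (95% confidence interval -0.17 to 0.24). This leaves the explanation open, because the probe sets may read different parts of the transcript. A histocompatibility haplotype shared by the knock-in leukaemias would part other H2 genes, of which 5 of 28 (17.9%) did not overlap between genotypes, against 2485 of all 19152 genes and 10% by chance (Fisher exact p = 0.40), so it also stays open. A genotype effect on this gene was not tested apart from these.

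Other splits of the same samples were counted for each comparison of genes. For 3 against 3 the 10 splits are too few for a share under 0.05. In c-kit-positive cells the genotype gave 27 genes and the highest other split 1, in c-kit-negative cells 12 and 2, and over both fractions 5 and 1. For c-kit, wild-type leukaemias gave 147 and 1, and those labelled knock-in 360 and 0. For the interaction all 10 splits gave 0 genes. Over both genotypes, 2 of 100 drawn splits gave at least as many genes as the 1580 of the c-kit fractions, the real one included. Such a count was rare among the splits, but the real split did not give the highest. The highest other split, with 2936 genes, exchanged only the c-kit-negative array of leukaemia 81 and the c-kit-positive array of leukaemia 85. On the main axis of variation between arrays (principal component 1, 41.2% of the variance) they lay at -0.17 and 5.18. The other c-kit-positive arrays lay at -31.1 to -6.27 and the other c-kit-negative arrays at 1.11 to 42.6. This exchange parts the arrays fully on that axis, but whether that gave the higher count was not tested. Of the 32 splits that part every pair, 1 gave as many, the real one, and the highest other gave 0. That is the smallest share that 32 splits allow.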
